A study of Arabidopsis thaliana and Zea mays with 12 samples.

How the data were processed

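The samples were 12 one-colour Affymetrix arrays of biotin-labelled RNA from leaves or aerial parts of 2-week-old plants. The plants were harvested near the middle of the light period. Arabidopsis RNA was run on the ATH1 array and maize RNA on the Maize Genome Array. Maize plants grew at 22 °C under a 16 h photoperiod after 2 days of imbibition, per the labels' protocols. Groups and replicate numbers came from the sample titles, with 3 arrays for each of Ag, Br, B73 and B97. RNA of replicated plants was pooled before labelling, per the labels' protocols, so the p-values measure the spread between pools.

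The deposited values are probe set intensities on a linear scale. On every array the mean over all probe sets, with the lowest and highest 2% left out, equals 100, so the arrays had been scaled to that mean before deposit. The software and the method that summarised probes into probe sets are not given in the sources used here. Detection calls and scanner files were not used here, so a low intensity cannot be called absent. 0 columns of per-sample values lacked a sample.

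The manufacturer's control probe sets (names starting with AFFX) were removed, 64 from the Arabidopsis arrays and 113 from the maize arrays. Values were tested as log2(intensity + 16), so a fold change is on that scale and understates the change of dim genes. After this step the column medians ranged from 5.59 to 5.74 in Arabidopsis and from 5.64 to 5.81 in maize. A gap of over 0.1 had been set before the data were examined as the condition for quantile normalization between the arrays of a species, so it was applied, and the values as deposited served as an alternative. Signals in the text are the deposited intensities, mean ± SD. The median log2 change of all probe sets was -0.0018 in Arabidopsis and 0.032 in maize, and neither other scaling moved it by over 0.1.

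Each species was fitted alone with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Directions are Br minus Ag and B97 minus B73. Gene lists were tested with camera at a preset correlation of 0.01, using the probe set of highest mean for each gene, and beside it with an estimated correlation and with fry. A list needed at least 3 measured members. On simulated arrays with the real means and spreads and 200 changed probe sets, the fit recovered 52% of the 2-fold and 88% of the 4-fold changes for Arabidopsis, with 2 false calls among 142. For maize it recovered 73% and 94%, with 6 false calls among 173. The changed probe sets were drawn from those brighter than every array's median, and the noise was independent between probe sets. These shares therefore do not cover dim probe sets or deviations shared across a whole array. The share recovered at an adjusted threshold also depends on how many probe sets change. The 200 planted are far fewer than the 3646 called on the real maize arrays. Plots were drawn with matplotlib 3.10.9.

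Genes were named from the GEO platform annotation tables supplied with the data. In Arabidopsis, 13513 probe sets had 1 gene, 503 several and 8730 none listed, and 1579 had a symbol that names a gene rather than a locus code. Arabidopsis symbols were updated through the gene identifier with the TAIR10.1 gene table. In maize, 1452 probe sets had 1 gene, 1 had several and 16168 had none listed, and 153 had a symbol other than a LOC number. Of the 473 and 3646 calls, 48 and 27 had such a symbol, so the named genes are a small part of what changed. Most lists fixed in advance therefore had too few annotated members. The clock, salicylic acid, jasmonate and cell cycle lists of Arabidopsis held 1 or 2 measured genes and were not tested, the nitrogen list of maize held 1, and the remaining lists held 0.

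The genes named were chosen by a rule set before the data were examined. It took, per species, the 7 called genes with a symbol and the largest log2 change in each direction whose groups did not overlap. It added the 2 largest called members of each fixed list, and, whatever their p, 10 Arabidopsis and 4 maize genes fixed by name. Of these, GI and AOP3 alone had an annotated probe set. Where a gene had several probe sets the one of highest mean is given. Further genes are named as called members of lists, or where stated as chosen after their values were seen.

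Same-numbered maize arrays deviated together from their group means (correlations across probe sets of 0.35, 0.21 and 0.53), which is taken as pairing. That pairing comes from the values, since the labels do not say that a number marks a shared day. The Arabidopsis numbers did not pair the arrays by this check. Alternatives covered the replicate number as a block, the scaling, the pseudocount, filters on dim probe sets, eBayes with a trend, with and without robust fitting, array weights, the choice of probe sets, a stricter threshold, and each array left out in turn. Leaving out both first arrays in Arabidopsis or the third array of both lines in maize was chosen after the files were seen; the added gene lists were written after the files were seen and before any gene was tested.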

Results

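Transcript levels were measured in leaves or aerial parts of 2-week-old plants of 2 species. In Arabidopsis thaliana, 3 arrays of the phenotype labelled Ag were set against 3 of the phenotype labelled Br. In maize, 3 arrays of B73 were set against 3 of B97, a pair of inbred lines. Each array held RNA pooled over replicated plants. The labels call the arrays of a group biological replicates. The Arabidopsis arrays carried 22746 probe sets and the maize arrays 17621, with the manufacturer's controls left out. Values are array intensities, so precision is limited by the number of arrays. The median probe set read between 32.3 and 37.5 on the Arabidopsis arrays and between 33.7 and 40.3 on the maize arrays. The protocols mention field trials of hybrids, but no hybrid was among the 12 arrays, so each comparison is between the 2 groups of a species.

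The first comparison asked which transcripts differed between Br and Ag. The thionin gene THI2.2, which encodes a small cysteine-rich antimicrobial peptide, had the largest rise of the called genes with a symbol. Its signal went from 10.8 ± 6.59 in Ag to 1115 ± 355 in Br (SD, n = 3), a log2 change of 5.38 ± 0.31 (SE, limma adjusted p = 7.2e-04). CSA1, an immune receptor gene of the TIR-NBS-LRR class, rose from 5.49 ± 2.36 to 144 ± 21.2 (log2 change 2.84, adjusted p = 7.2e-04). ATB2, of the aldo-keto reductase family, was the most reduced of the called genes with a symbol, from 276 ± 9.19 in Ag to 32.9 ± 5.16 in Br, a log2 change of -2.60 ± 0.12 (adjusted p = 3.5e-04). ETFBETA, for a subunit of the mitochondrial electron transfer flavoprotein, and ETFQO, for the oxidoreductase that accepts its electrons, fell, with log2 changes of -2.32 (adjusted p = 0.0032) and -1.91 (adjusted p = 0.041). The other subunit gene, ETFALPHA, read 79.1 ± 4.67 in Ag and 86.2 ± 4.41 in Br and did not pass (adjusted p = 0.86).

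Several genes that act on the cell wall rose in Br. The expansin-like gene EXLA1 rose from 49.2 ± 28.9 to 231 ± 83.3 (log2 change 1.92, adjusted p = 0.040). The xyloglucan endotransglucosylase genes XTH33 and XTH16 rose by 1.92 and 1.49 on the log2 scale (adjusted p = 0.045 and 0.040). Of the 28 measured expansin and xyloglucan endotransglucosylase genes, 4 rose, the fourth being EXPB1, and 0 fell; 24 did not pass the test. As a group they missed the threshold (camera adjusted p = 0.088, and 0.71 with an estimated correlation). They passed camera without the dimmest probe sets (adjusted p = 0.0080), without the third Ag array (0.022) or with the replicate number as a block (0.027). Of 45 endoglucanase, cellulose synthase-like and wall acetylation genes, 1 rose, the endoglucanase GH9C2 (log2 change 1.14), and 0 fell. That group passed with a preset correlation (camera adjusted p = 0.034) but not with an estimated one (adjusted p = 0.71), and it missed without the first or the second Ag array or the second or the third Br array (adjusted p up to 0.10).

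A pair of plastid genes rose in Br. The cytochrome b6f subunit gene petN rose from 44.1 ± 35.9 to 441 ± 96.2 (log2 change 3.04 ± 0.38, adjusted p = 0.013), and rbcL, for the large subunit of Rubisco, rose from 197 ± 57.8 to 506 ± 77.9 (log2 change 1.33, adjusted p = 0.033). These were the 2 genes that passed the test among 33 measured plastid genes of the photosystems, the cytochrome complex, ATP synthase and Rubisco. The log2 change of 24 of the 33 was positive, with a median of 0.24; it was 19 with values as deposited, with a median of 0.12, and 18 with median centring, with a median of 0.051. The group passed camera with a preset correlation (adjusted p = 0.0034), not with an estimated one (adjusted p = 0.71), and it missed with values as deposited (adjusted p = 0.34) or without the second Ag array (adjusted p = 0.10). By fry its adjusted p was 0.27. Of 10 plastid genes of the NADH dehydrogenase-like complex and 19 of plastid ribosomal proteins and RNA polymerase, 0 passed by limma, with 1 and 5 at an unadjusted p under 0.05 (camera adjusted p = 0.71 and 0.091; 0.83 and 0.71 with an estimated correlation). The latter list passed camera without the first Ag array (adjusted p = 8.3e-05), without the second Br array (0.038) or without the first array of both groups (0.012). With the replicate number as a block it passed too (0.047). Of 16 genes of the mitochondrial genome 0 passed by limma, with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.30; 0.71 with an estimated correlation), and this list also passed without the first Ag array (adjusted p = 0.034). The wall, plastid and mitochondrial lists were written after the probe annotation had been read and before any gene was tested. At least 2 of the lists written later passed camera in 5 of the 10 splits of the arrays, the real one included.

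The remaining named genes lower in Br were of varied function. MSRB5, a methionine sulfoxide reductase gene, fell from 181 ± 40.9 to 40.1 ± 3.83 (log2 change -1.81, adjusted p = 0.0060). CYTC6A, for a cytochrome of the thylakoid lumen, fell from 449 ± 60.1 to 126 ± 23.7 (log2 change -1.71, adjusted p = 0.0061). UGT72E1, a glucosyltransferase gene of phenylpropanoid metabolism, and bHLH121, a transcription factor gene of the iron response, fell by 1.45 and 1.43 on the log2 scale (adjusted p = 0.040 and 0.034). The drought-induced gene DI21 was higher in Br, at 80.4 ± 19.6 against 12.9 ± 4.59 (log2 change 1.68, adjusted p = 0.012).

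**Figure D1:**
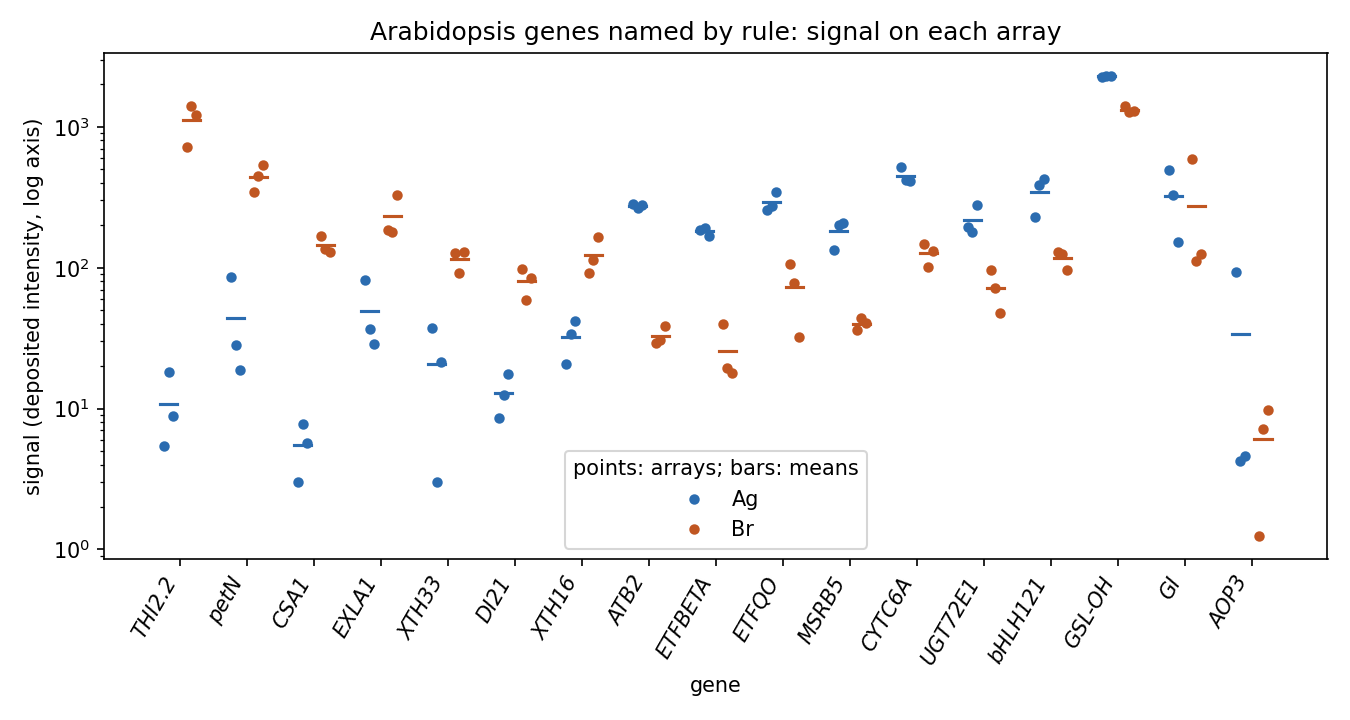
Signal on each of the 6 Arabidopsis arrays for the genes named by the rule, with the deposited intensity on a log axis, 1 point per array and a bar at each group's mean. THI2.2 stands at a mean of 1115 in Br against 10.8 in Ag, while the Ag and Br points of GI and AOP3 overlap.

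Among the lists fixed in advance, GSL-OH, which hydroxylates alkenyl glucosinolates, was the 1 member that passed over all probe sets. Its signal fell from 2282 ± 14.9 in Ag to 1326 ± 62.0 in Br (log2 change -0.66, adjusted p = 0.032). It was also the 1 of 6 measured glucosinolate synthesis genes to pass when adjusted over the list alone. The other 5 included AOP3, at 34.0 ± 51.2 in Ag and 6.08 ± 4.40 in Br, which missed the threshold (log2 change -0.78, adjusted p = 0.60). The AOP3 mean in Ag rests on the first array, at 93.2 against 4.25 and 4.62, and without that array the log2 change was 0.010. The clock and flowering gene GI read 324 ± 170 in Ag and 276 ± 275 in Br, a difference within the spread of the arrays (adjusted p = 0.80). By limma 0 genes passed, over all probe sets or adjusted over the list alone, among 4 flowering time, 3 nuclear photosynthesis, 4 cold response, 4 flavonoid, 3 root marker and 4 epidermis and stomata genes. 0 of these 7 lists passed camera (lowest adjusted p = 0.69), fry (0.074) or camera with an estimated correlation (0.90). At an unadjusted limma p under 0.05, 2 of the 28 members passed. Over the 6 glucosinolate genes the median log2 change was 0.14 and the mean -0.12, and camera's direction was lower (adjusted p = 0.89). With values as deposited, 1 list passed, nuclear photosynthesis (adjusted p = 0.036), whose members RCA, LHCB4.1 and PSAE-1 had log2 changes of -0.36, -0.38 and -0.33 on that scale against -0.017, -0.0042 and 0.056 after quantile normalization. A list of 28 nuclear photosynthesis and chlorophyll genes, written later, passed on the deposited scale too, with a median log2 change of -0.28 (adjusted p = 0.0033). With median centring, where camera was not run, the medians were -0.35 for these 28 genes and -0.43 for the list of 3. After quantile normalization the median of the 28 was -0.025 and they missed the threshold (adjusted p = 0.52; 0.76 with an estimated correlation). Of the 28, LIL3:1 alone passed, lower in Br (log2 change -0.89, adjusted p = 0.048), and it missed without any array but the first of Br (adjusted p up to 0.17).

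Over all 22746 probe sets, 473 passed an adjusted p of 0.05, 219 higher and 254 lower in Br, and 306 of them changed at least 2-fold, 139 higher and 167 lower. The groups did not overlap for 20.4% of probe sets, where chance gives 10%, and 3661 had an unadjusted p under 0.05. The 3'/5' signal ratio of control transcripts, a sign of RNA quality, moved with the groups. For ubiquitin it was 2.04 ± 0.30 in Ag and 1.04 ± 0.15 in Br, and for actin 2.06 ± 0.25 and 1.53 ± 0.29, with every Ag array above every Br array (two-sided exact permutation p = 0.10 for each, the smallest that 3 against 3 allow). The ratio overlapped between groups for GAPDH. On the first principal component, which held 45.5% of the variance, the first Br array lay at 5.57, between the Ag arrays (-32.8 to -24.6) and the other Br arrays (34.5 and 42.6). The count was 237, 119 and 143 without the first, the second or the third Ag array, and 884, 105 and 110 without the first, the second or the third Br array; 533 passed when the first array of each group was left out. Weighting the arrays by quality gave 889, and a pseudocount of 1 gave 148. Of the genes named above, ATB2, ETFBETA, CSA1, THI2.2, MSRB5 and CYTC6A passed without any one array, while 9 others depended on the arrays kept. ETFQO, GSL-OH, UGT72E1 and XTH16 missed the threshold without any array but the first of Br (adjusted p up to 0.15), and XTH33 without any but the first of Ag (up to 0.17). EXLA1 and bHLH121 missed without the second or the third array of either group (up to 0.15), petN without the second Ag, the second Br or the third Br array (up to 0.076), and DI21 without the second Ag or the third Br array (up to 0.075). Among the list members, rbcL missed without the second or the third array of either group (up to 0.13), EXPB1 without any array but the first of Br (up to 0.17), and GH9C2 without any one array (up to 0.18). A sequence difference under a probe set would change its signal too, and this was not tested in Arabidopsis. All the named Arabidopsis changes carry that limit. It covers the near on-off signals of THI2.2 and CSA1, and the falls of ATB2 and ETFBETA, each read by 1 probe set.

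**Figure D2:**
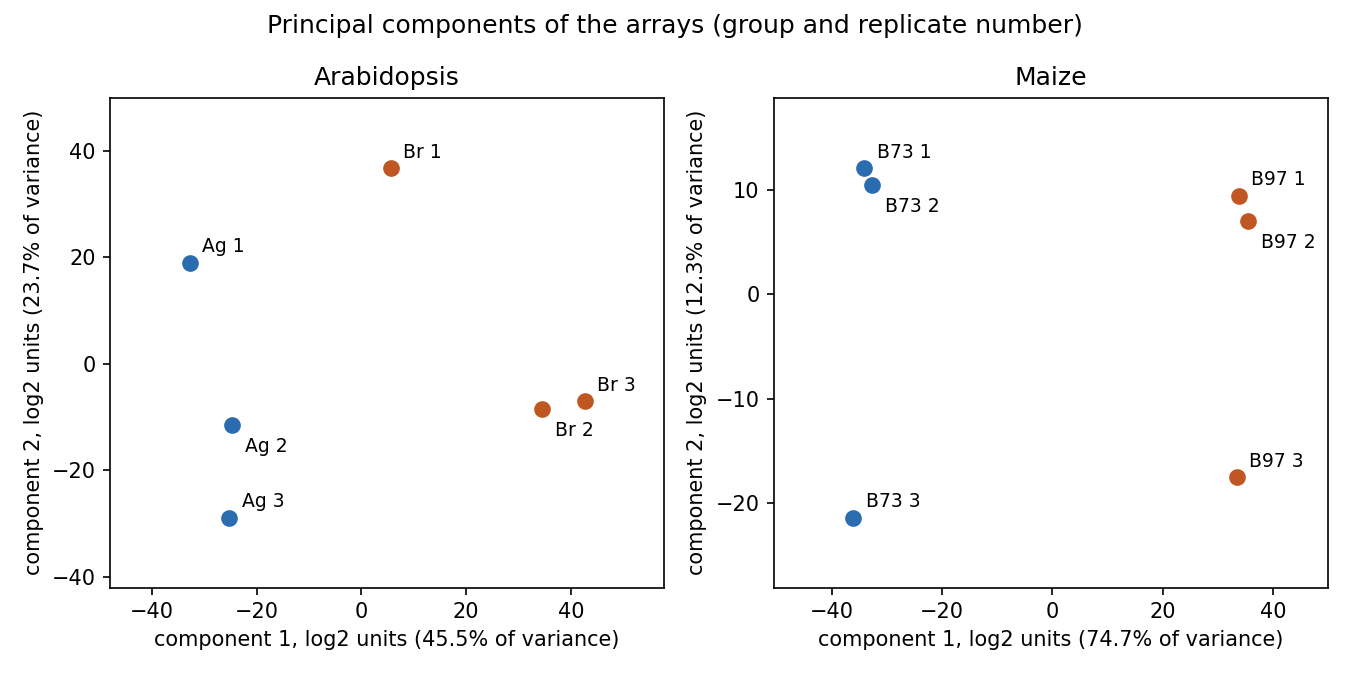
Principal components of the log2 values after quantile normalization, with component 1 across and component 2 up, both in log2 units, and 1 point per array. The first component separates the groups in both species, the first Br array lies at 5.57 between the groups, and in maize the third array of each line stands apart on component 2, which holds 12.3% of the variance.

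The second comparison asked which transcripts differed between B97 and B73. Among lipoxygenase and jasmonate genes, calls went in both directions. The allene oxide cyclase gene aoc1 fell from 226 ± 29.4 in B73 to 11.7 ± 2.83 in B97, a log2 change of -3.09 ± 0.13 (SE, n = 3, limma adjusted p = 1.9e-05). Its second probe set fell as well (log2 change -1.89). The 12-oxo-phytodienoate reductase gene opr7 fell from 114 ± 21.5 to 55.2 ± 9.52 (log2 change -0.84, adjusted p = 0.0039), and the lipoxygenase gene lox3 rose from 17.5 ± 4.18 to 54.4 ± 10.2 (log2 change 1.14, adjusted p = 7.9e-04). The beta-tubulin gene TUBB2 had the largest rise of the called genes with a symbol, from 33.3 ± 12.6 to 115 ± 28.6 (log2 change 1.48, adjusted p = 0.0031).

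Among the other named genes lower in B97, the expansin gene expA4 fell from 124 ± 1.71 to 35.9 ± 4.86 (log2 change -1.39, adjusted p = 7.9e-05). Its other 2 probe sets had log2 changes of -0.47 and -0.27 and missed the threshold, but passed with the arrays paired by replicate number (adjusted p = 0.021 and 0.050). The peroxidase gene PER42 fell by 1.06 on the log2 scale (adjusted p = 0.0020), the nitrate reductase gene NNR1 by 0.83 (adjusted p = 0.011) and the methionine S-methyltransferase gene MMT1 by 0.67 (adjusted p = 0.0054). The gene listed as nar fell from 113 ± 21.0 to 20.3 ± 7.22 (log2 change -1.79, adjusted p = 3.0e-04). A second, dim nar probe set at 2.31 and 3.33 had a positive log2 change of 0.087 that missed the threshold. The rises beyond TUBB2 and lox3 were small: lls1, which acts in chlorophyll breakdown, rose by 0.70 on the log2 scale, IDI2 by 0.60, the phosphate transporter gene pht1 by 0.60, the aldehyde oxidase gene AO1 by 0.53 and the copalyl diphosphate synthase gene CPPS2 by 0.46, from a signal of 3.40 ± 1.01 to 9.91 ± 3.11. Adjusted p for these 5 ran from 0.0010 to 0.025.

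**Figure D3:**
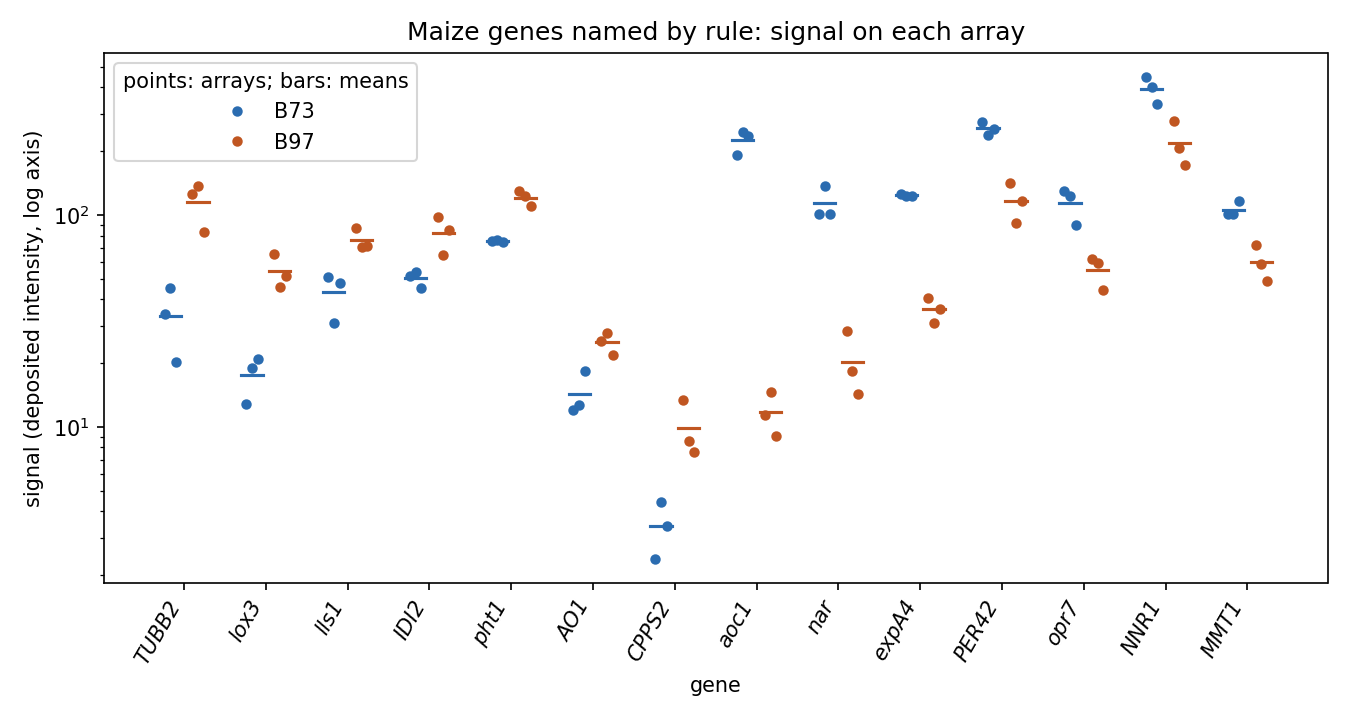
Signal on each of the 6 maize arrays for the genes named by the rule, with the deposited intensity on a log axis, 1 point per array and a bar at each line's mean. The aoc1 mean is 226 in B73 and 11.7 in B97, and the B73 and B97 points of every gene shown are apart, as the rule required.

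The lipoxygenase and jasmonate list was the 1 maize list fixed in advance with enough annotated members to test. Of its 6 measured genes, 1 rose, 1 fell and 4 did not pass, and adjusted over the list alone 2 rose and 1 fell. The second rise in that count was the allene oxide synthase gene aos1 (log2 change 0.49, adjusted p = 0.051 over all probe sets; 0.022 with the arrays paired). The list was not shown to move in 1 direction (camera p = 0.55; 0.68 with an estimated correlation; fry p = 0.22), while fry's test for changes in either direction gave p = 5.5e-04. That either-direction test does not compare a list with the other probe sets, and 20.7% of all maize probe sets were called. The methyl-CpG-binding list described below, with 1 call among 7 genes, passed it too. The zein and exchanger lists, with 0 calls, did not. The result thus does not set the jasmonate list apart. A list of all 9 lipoxygenase and jasmonate genes that the annotation names, written later, added aoc1 and had 1 rise and 2 falls. Its median log2 change was 0.0069 and its mean -0.23. The other lists written later held 7 methyl-CpG-binding domain genes, of which mbd105 rose (log2 change 0.42, adjusted p = 0.012), 8 endosperm zeins and 3 sodium-hydrogen exchangers, of which 0 passed by limma, at an unadjusted p under 0.05 as well. The zeins were dim, with means of at most 18.5 in either line. Camera gave an adjusted p of 0.96 for each of these 4 lists, and 0.97 with an estimated correlation.

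Over all 17621 probe sets, 3646 passed an adjusted p of 0.05 by limma, 1758 higher and 1888 lower in B97. Among the 910 that changed at least 2-fold, 301 were higher and 609 lower. The groups did not overlap for 37.2% of probe sets, where chance gives 10%. The probe sets with the greatest rises have no listed gene. In the other direction, LOC542467, singled out after its values were seen, fell from 1934 ± 571 to 45.3 ± 10.3, and its second probe set from 1174 ± 155 to 63.8 ± 22.5. The third array of each line stood apart on the second component. The 99th percentile of signal there was 1735 in B73 and 1937 in B97, against 1090 to 1284 on the other 4 arrays. Without both, 2814 probe sets passed. The second B73 array had the highest 3'/5' ratio of the 6 for actin (11.4), elongation factor (5.57), GAPDH (5.91) and cyclophilin (3.80), though not for ubiquitin. For GAPDH the ratio moved with the lines, at 3.91 ± 1.78 in B73 and 2.09 ± 0.31 in B97 without overlap (two-sided exact permutation p = 0.10). The ratios of actin, elongation factor, cyclophilin and ubiquitin overlapped between the lines (two-sided exact permutation p from 0.50 to 0.90). Mean ratios of cyclophilin and ubiquitin were higher in B97, and those of actin and elongation factor in B73. The actin ratio was at least 4.89 on every maize array. Leaving out the second B97 array lowered the count to 2331. The calls of 5 named genes depended on the arrays kept. CPPS2 missed the threshold without the first or the third B73 array or the first or the second B97 array (adjusted p up to 0.071), IDI2 without the third B73, the first B97 or the third B97 array (up to 0.069), lls1 without any one B97 array (up to 0.074), and NNR1 and mbd105 without the second B97 array (0.050 and 0.052).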

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

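Leaving out both first Arabidopsis or the third array of both maize lines was chosen after the data were seen; the added lists were written after the files were seen and before any gene was tested. Of 15 named and called Arabidopsis genes, 6 kept their call under all 20 alternatives and 9 lost it under at least 1. In maize 10 of 14 kept it under every alternative that held their probe set, 19 for lox3 and AO1 and 20 for the others. The sign of these 29 genes changed in 0 cases. The cause of the moves was not tested, except that a stricter threshold passes fewer by construction. Fewer arrays did not always pass fewer: without the first Br array the Arabidopsis count rose from 473 to 884. In Arabidopsis the replicate numbers did not pair the arrays (correlations of 0.32, 0.029 and 0.11, and not every array correlated best with its own number), and a replicate block gave 347 calls against 473, with 291 shared. Under it ETFQO, EXLA1, bHLH121, GSL-OH, EXPB1, GH9C2, LCR68, LIL3:1 and the 4 called UDP-glycosyltransferase genes did not pass (adjusted p from 0.053 to 0.099). In maize, where the numbers paired, the block gave 4820 against 3646, with 3582 shared, and every named gene and list kept its side of the threshold but aos1 and the lesser expA4 probe sets. The Arabidopsis count was 148 with a pseudocount of 1, 889 with array weights, 289 with 1 probe set per annotated gene and 111 at an adjusted p under 0.01. The 2-fold count of 306 became 148 with a pseudocount of 1, 107 with 64, 174 with 1 probe set per gene and 109 at 0.01. With 1 array left out, the counts ran from 105 to 884 and from 105 to 529. The fixed lists passed in 0 of 7 cases, and 1 with values as deposited. Of the added lists 2 passed, against 0 with an estimated correlation, 1 with fry (serine carboxypeptidase-like), 4 with a replicate block, 3 without the dimmest probe sets (the lowest 25% by mean), 3 without both first arrays, and 0 to 3 with 1 array left out. The maize count was 2257 without probe sets under the median signal, 239 with 1 probe set per gene, 2020 at 0.01, and 2331 to 3217 with 1 array left out. Its 2-fold count of 910 became 578 without those under the median, 1760 and 346 with pseudocounts of 1 and 64, and 53 with 1 probe set per gene. On each array 33.7% to 38.7% of probe sets read below 16, where the pseudocount damps the fold.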

Other observations

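The tests of scaling, of Ag RNA in the first Br array and of a state shared by the first arrays were chosen after the result was seen. Members of further Arabidopsis families passed the test. Of 47 UDP-glycosyltransferase genes, UGT76E11 rose by 0.81 on the log2 scale and UGT72E1, UGT73B1 and UGT84A3 fell, the second by 1.27 and the last by 0.64. Of 19 CYP71B cytochrome P450 genes, CYP71B24 rose (log2 change 1.04) while CYP71B23 and CYP71B37 fell (-1.10 and -0.87). Of 29 serine carboxypeptidase-like genes, SCPL34 and scpl50 fell, by 1.25 and 1.22 on the log2 scale, and 0 rose. Camera adjusted p values for these families were 0.30, 0.61 and 0.22, and 0 of the 3 passed with an estimated correlation. The carboxypeptidase-like list passed fry (adjusted p = 0.014). Of 15 plant defensin and thionin genes, LCR68 rose besides THI2.2, 13 did not pass and 0 fell (camera adjusted p = 0.30; 0.71 with an estimated correlation). Each of these calls but that of THI2.2 was lost without at least 4 of the 6 arrays in turn, with adjusted p up to 0.16. Of 17 pollen and 12 ovule and seed genes, 0 passed by limma, with 1 and 2 at an unadjusted p under 0.05. Of all 19 lists written later, 2 passed camera with a preset correlation and 0 with an estimated one. The greatest changes at genes known only by a locus code, singled out after their values were seen, were AT2G25510, from 3916 ± 369 in Ag to 10.3 ± 5.44 in Br, and AT3G22240, from 46.1 ± 30.9 to 1129 ± 226. Whether a sequence difference under the probes adds to them was not tested.

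ETFBETA and ETFQO carry electrons from the breakdown of branched-chain amino acids. A hypothesis was that other genes of that breakdown and of its electron transfer are lower in Br, and 5 genes were taken. The breakdown genes IVD (log2 change -1.49, limma adjusted p = 0.052), MCCA (-2.14, adjusted p = 0.14) and MCCB (-0.66, adjusted p = 0.31) were negative. ETFALPHA and D2HGDH, taken with the electron transfer, were at 0.060 and 0.14. The median was -0.66 but 0 of the 5 passed alone and limma's fry over the 5 missed the threshold, while its test for changes in either direction passed, so the hypothesis stays open. MCCA read 414 on the first Br array against 93.0 and 63.3 on the others, and 552 to 872 in Ag.

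The first Br array lay between the groups, 0.50 of the way from the other Br arrays to the Ag mean on the first component. Ag RNA in that sample or a wrong label was tested as a share of linear signal. The position is on log2 values, so it does not give the share that a mixed sample would need. Over 28 probe sets bright in Ag and at least 4-fold lower on the other Br arrays, the median Ag share was 0.029 (95% interval 0.0065 to 0.098), which argues against a share near 0.50 but not against a small one; over 26 probe sets bright on the other Br arrays and dim in Ag, the loss on the first Br array came to a share of 0.24 (0.024 to 0.45), with 0.046 and -0.079 for the other Br arrays. By 3'/5' ratios, 0 of 3 control transcripts lay over 1.5-fold outside the range of the other arrays. That range spans both groups, whose ratios differed, so it cannot decide on an RNA quality between them. The ubiquitin ratio of the first Br array was 1.21, against 0.91 and 1.01 on the other Br arrays and 1.76 to 2.35 in Ag. Its GAPDH ratio of 0.80 was the highest in Br and within the Ag range. Its actin ratio of 1.64 lay between those of the other Br arrays. RNA quality thus stays open. A state shared by the first arrays of both phenotypes may account for part of the position of the first Br array. Of the 500 probe sets where it stood farthest from the other Br arrays, the first Ag array deviated the same way in 86%. The same count gave 55.2% and 63.6% for the second and the third arrays.

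Named genes chosen after their values were seen show part of what set the first arrays apart. The cold-regulated COR27 read 242 on the first Ag array and 207 on the first Br array, against 0.81 to 27.2 on the other 4. COR15A read 1539 and 1444 on the first arrays and 173 to 730 on the others. GI, which peaks late in the day, read 493 and 594 on them and 111 to 326 elsewhere. PWD, for a phosphoglucan, water dikinase of starch breakdown, read 578 and 630, against 119 to 214. Other large deviations of the first Br array were little shared or opposite in the first Ag array: 2.78 against 0.37 on the log2 scale for GH3.3, 2.27 against 0.48 for MGL, 2.17 against 0.39 for PYK10 and 2.26 against -0.37 for MCCA. A later hour of harvest or cooler growth are candidate explanations for these genes only as hypotheses. The 86% counts probe sets on the same side in both first arrays and does not tell one state from another. The labels place every harvest near the middle of the light period, give no hour or temperature for Arabidopsis, and neither was tested.

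In maize, 609 of the 910 probe sets past 2-fold were lower in B97. The lower share was at least 63.0% under quantile normalization, median centring and the deposited scale. The choice among these scalings thus does not account for the direction. The share was lowest with median centring and highest on the deposited scale, so its size does depend on the scaling. This test of scaling was chosen after the result was seen. Sequence differences that weaken binding of the B97 transcript to a probe set stay open. Of 11 genes with a 2-fold lower call and a probe set of another target sequence, the other set was lower as well in 54.5% (exact 95% interval 23.4% to 83.3%). For higher calls it was 6 of 7 (two-sided Fisher's exact p = 0.32). The share met the sign of such differences set beforehand. Its interval is wide and Fisher's test does not separate the directions, so these genes are too few to decide. A true difference in expression or gene content between the lines, which the design names, also stays open and untested.

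Neighbouring genes in the TAIR10.1 gene order were asked whether they change together. Of 6006 neighbouring pairs among 13209 measured Arabidopsis genes, 4 were called in the same direction, where 10000 shuffles of the calls gave a median of 1 and a central 95% that reached 4. The one-sided permutation p was 0.038, but the count did not exceed the bound set for the test, which leaves the question open. 1 of the 4 pairs was ETFBETA and AT5G43440 (log2 changes of -2.32 and -1.76). Binding of similar copies to one probe set was not tested for these pairs.

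With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In Arabidopsis the real split gave 473 calls, 306 of them past 2-fold, and the highest other split gave 0 and 0, so 1 of the 10 was as large. In maize the real split gave 3646 and 910 and the highest other 0 and 0, again 1 of 10. Every other split mixes arrays of both groups, so a group difference enters its spread and lowers its count of calls. A count of 0 there is thus no independent support for the real split. These splits took no account of the maize pairing by replicate number. For the added Arabidopsis lists, 5 of the 10 splits passed at least as many lists as the real one, 2, which is itself 1 of the 5. The highest other passed 5, by setting the first Ag array and the first and the third Br arrays against the rest. The 2 passing lists thus do not set the real split apart.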
